A study of Mus musculus with 8 samples.

How the data were processed

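Nuclear RNA of forebrain excitatory neurons was sequenced from 4 mock-treated (Mock) and 4 pilocarpine-treated (Pilo) samples of male C57BL/6J mice carrying a Camk2a-driven Cre and a Cre-dependent SUN1-sfGFP nuclear tag. Libraries were directional and made from polyadenylated RNA, per the labels' protocols. The labels give groups and replicate numbers but do not say that each sample is a separate mouse, so p-values measure the spread between these samples, which may be technical in part. Pilo mice were kept by their seizure score, and no such selection applied to Mock mice.

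The values are raw read counts per gene as deposited by the authors. The submitters' processing notes name the mm10 genome, Trimmomatic 0.39, STAR 2.7.1a, HTSeq 0.11.2, R 4.1.1 and edgeR, with no roles. The annotation release, the strand setting of the counting and the way exonic and intronic reads were separated are not given in the sources used here. Reads of overlapping, antisense and closely related genes may therefore be shared, and the counts of such genes and of the microRNA loci are uncertain. The exonic table held 55471 Ensembl genes, of which 55144 matched a symbol and 19833 had 0 counts in every library; the unmatched 327 held 0.165% of counts. The second table held separate exonic and intronic counts for 18513 Entrez genes, of which 18507 matched a symbol. The design had assumed a sum of both regions in that table and an intronic count by subtraction. As the regions came separately, intronic counts were used directly, gene body counts were their sum with exonic counts, and no gene was left out for a negative difference. Genes without introns are not part of the intronic analysis. Coordinates are from GENCODE vM21 for the exonic table and from RefSeq for the second table, both on GRCm38, the build called mm10.

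Library columns were matched between the tables by the correlation of their deviations over genes, which exchanged numbers 2 and 3 in both groups. Replicates of a group differed by more than counting noise (chi-square per degree of freedom 9.27 to 30.7), so all 8 libraries were used as separate samples. Total counts are given with the data. With them, simulated changes were recovered in the exonic comparison (19251 genes) for 50.8% of genes changed 1.5-fold, 92.5% at 2-fold and 93.9% at 4-fold. For gene bodies (14849 genes) these were 65.7%, 95.5% and 98.5%, and for the difference between regions (13053 genes) 19.4%, 83.6% and 100%. Each of these simulations changed only 200 genes, while 31.8% of genes were called in the real exonic comparison. The adjusted threshold is stricter when few genes change, so these rates do not give the sensitivity in the real data. In simulated data with 1 moved list, camera called it and 0 of 22 lists that shared no moved gene. The simulated genes varied independently, at a dispersion of 0.02, so this check cannot tell how camera behaves when list members vary together. In the real data the correlation estimated for a function list reached 0.4096, for the cytosolic ribosomal protein genes.

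Genes were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F-test (robust), TMM normalization, filterByExpr with a minimum count of 10 and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was taken as the size of the fitted coefficient, without the prior count, divided by the square root of F. Exonic and intronic changes were compared as the interaction of region with treatment, with the sample as a covariate and a scaling factor per region. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted within the 24 function lists and within the 16 marker lists. Some genes, such as Homer1, Per1, Vgf and Cdkn1a, belong to several lists, so the list results are not independent of each other. The intronic share was compared by an exact permutation test. The comparisons, lists and rule for named genes were set before the data were examined. The rule took 11 genes fixed in advance, and the 12 largest rises and 12 largest falls among genes past the test. These needed a mean count of at least 50, no overlap of the groups and a symbol not of the Gm or Rik form. It also took up to 4 genes of smallest p per function list, and 6 genes per direction for exons against introns. Other list members named in the text were chosen after their values were seen. Some genes of the rule are covered by the counts of their lists and are not reported here by name.

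The replicate numbers of the titles are shared by the groups. Deviations from the group means correlated between same-numbered libraries in every pair (Pearson r 0.372, 0.380, 0.401 and 0.377), over the limit of 0.1 set for taking the numbers as pairs. The main fits nonetheless kept the planned model with treatment only, and the replicate number entered as a block only in an alternative. Calls, standard errors and list results given without the block therefore leave the pairs out. The second principal component (18.4% of variance) parted numbers 1 and 2 from 3 and 4 in both groups. Alternatives were RLE size factors, the Wald test of DESeq2 1.42.0, limma-voom, other filters on low counts, libraries thinned to equal depth, a replicate block, a minimum change of 1.5-fold (glmTreat), each library left out, a common scaling factor for both regions, an estimated correlation and fry for lists. Fits within the sets of replicate numbers, the alternatives for the intronic share, and the counts of list members under the alternatives were chosen after seeing the data.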

Results

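Nuclear polyadenylated RNA was measured in forebrain excitatory neurons of male mice during pilocarpine-induced seizure and in mock-treated mice, with 4 samples per group. Nuclei were captured by INTACT, in which a GFP-tagged nuclear envelope protein is switched on by Cre recombinase, here under a Camk2a promoter, and antibody-coated beads pull the tagged nuclei from a homogenate. Pilocarpine, a muscarinic acetylcholine receptor agonist, was given at 340 mg/kg, 30 min after 1 mg/kg of scopolamine methyl nitrate, a muscarinic antagonist that enters the brain poorly. The Pilo mice then had 100 min in which seizures developed, and those scoring 3 to 5 on the Racine scale of seizure behaviour were kept. The Mock mice received scopolamine and saline, and all mice were 6 to 8 weeks old. Levels are given as CPM, counts scaled to the library's total after TMM normalization. The exonic count table held between 29356788 and 36161448 counts per library. In the second table, the exonic columns held between 27135364 and 33715773 counts and the intronic columns between 11928054 and 16703475. The columns numbered 2 and 3 were exchanged between the tables in both groups, judged by their correlation over genes, so replicate numbers below are those of the table in question.

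The comparison of Pilo with Mock asks which transcripts of excitatory neuronal nuclei differ after pilocarpine, during acute seizure. Every Pilo sample had both the drug and seizures, and the Mock samples had no pilocarpine. Direct effects of the drug therefore cannot be told apart from those of seizure. Transcription factor genes of the immediate early class were among the largest rises. Fos (ENSMUSG00000021250, GRCm38 chromosome 12, 85473890 to 85477273), a subunit of the AP-1 transcription factor, went from 14.8 ± 9.83 to 138 ± 32.8 CPM (SD, n = 4 each), a log2 fold change of 3.23 (SE 0.46, adjusted p = 0.00228 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fosb rose by 3.71 (SE 0.27), Npas4, a neuron-specific activity-dependent factor, by 2.06 (SE 0.27), Egr1 by 2.09 (SE 0.32) and Nr4a1, an orphan nuclear receptor, by 1.61 (SE 0.23). Arc (ENSMUSG00000022602, chromosome 15, 74669083 to 74672570), which regulates AMPA receptor endocytosis, rose from 133 ± 77.0 to 550 ± 59.9 CPM (SD, n = 4 each). Bdnf, a neurotrophin, rose by 0.81 (SE 0.21) and Crem, a cAMP-responsive factor, by 0.48 (SE 0.11). Among the genes fixed in advance, Camk2a, Slc17a7 and Crtc1 did not pass the test, with log2 fold changes of 0.20 (SE 0.11), -0.13 (SE 0.09) and 0.17 (SE 0.09). With the replicate number as a block they passed, at adjusted p = 0.00412, 0.0493 and 0.0106. In Mock replicate 4, Fos stood at 29.2 CPM and Arc at 244 CPM, the highest of the Mock libraries.

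**Figure D1:**
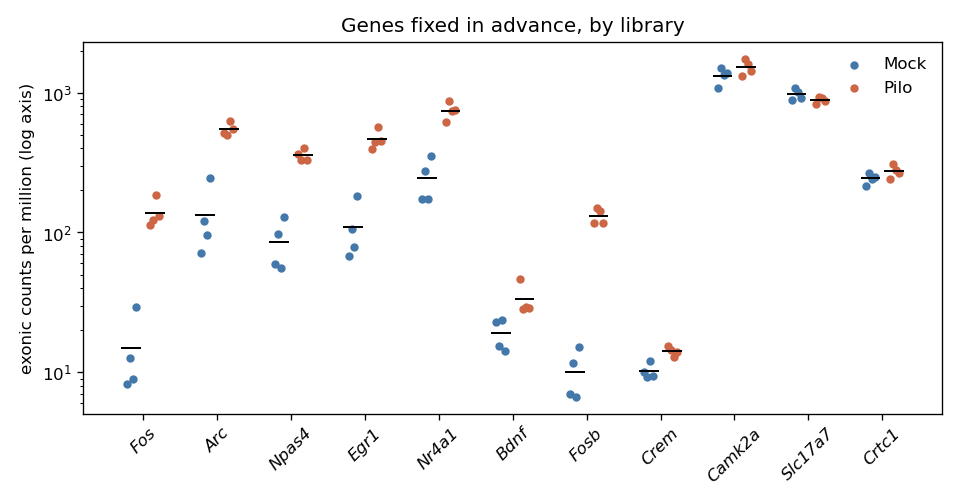
Exonic CPM (log axis) of the 11 genes fixed in advance, with a point per library and a line at each group's mean (4 Mock and 4 Pilo libraries). Fos means were 14.8 CPM in Mock and 138 CPM in Pilo, while Camk2a, Slc17a7 and Crtc1 passed only with the replicate number as a block.

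Of 27 measured immediate early transcription factor genes, 26 rose and 0 fell, with the same 26 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.56e-38). The largest rises of all genes named by rule were Atf3, a stress-responsive factor, at 4.63 (SE 0.29), Ccn1, a secreted matricellular protein, at 4.51 (SE 0.37), and Maff, a small Maf factor, at 4.11 (SE 0.30). Maff stood at only 0.199 to 0.402 CPM in Mock, against 3.34 to 7.05 CPM in Pilo, so the size of its rise rests on few Mock reads. Egr4 rose by 3.39, Egr2 by 3.11 and Junb by 2.99, and Nr4a2 by 1.93 (SE 0.10). Klf6 was the member that did not rise, at -0.33 (SE 0.12, adjusted p = 0.0586). Counts over the microRNA loci Mir132 and Mir212, which are neighbours on chromosome 11, rose by 3.38 (SE 0.32) and 3.19 (SE 0.48). In this polyadenylated RNA they are counts over the loci, not levels of the mature microRNAs. Without Mock replicate 4 or Pilo replicate 1, 1 early factor gene was lower past the test.

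Other genes induced by neuronal activity also rose. Of 40 measured activity-induced effector genes, 37 rose and 0 fell, with 37 higher adjusted over the list alone (camera adjusted p = 1.75e-49). Gadd45g, linked to DNA demethylation and stress signalling, rose by 2.88 (SE 0.15), Sik1, a salt-inducible kinase, by 2.73 (SE 0.18), Ifrd1 by 1.37 (SE 0.10) and Rgs2, a regulator of G-protein signalling, by 1.25 (SE 0.08). Tiparp, a PARP family enzyme, rose by 3.15 (SE 0.23) and Thbs1, a thrombospondin, by 3.28 (SE 0.18). Of 24 targets of CREB and cAMP, 21 rose and 0 fell, with 23 higher adjusted over the list alone (camera adjusted p = 4.87e-29), among them Irs2 at 1.76 (SE 0.09). This list shares Fos, Junb, Egr1, Nr4a1, Nr4a2 and Nr4a3 with the early factor list. It also shares Sik1, Per1, Bdnf, Pcsk1, Vgf and Rgs2 with the effector list, so it is not an independent result. Of 19 MAP kinase phosphatases and feedback inhibitors, 14 rose and 0 fell, with 15 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.09e-17). Errfi1, an inhibitor of EGF receptor signalling, rose by 1.74 (SE 0.08), and the ERK phosphatase genes Dusp6 and Dusp5 rose by 1.75 (SE 0.13) and 2.20 (SE 0.16). These 4 lists also passed with an estimated correlation, at adjusted p values from 0.00266 to 0.00277. Without Pilo replicate 1, the effector, CREB and MAP kinase lists each had 1 gene lower.

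Secreted signals and stress genes rose in part. Of 24 neuropeptide and dense core vesicle genes, 12 rose and 1, Nucb2, fell, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.13e-05, and adjusted p = 0.0624 with an estimated correlation). The granins Vgf, Chga and Chgb rose by 0.82 (SE 0.09), 0.71 (SE 0.09) and 0.55 (SE 0.08). Of 27 growth factors and receptors, 8 rose and 0 fell, with the same number adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.249 with an estimated correlation). They included Acvr1 at 0.85 (SE 0.09), Igf1 at 1.30 (SE 0.19) and Hbegf at 0.91 (SE 0.15). Of 30 heat shock and unfolded protein response genes, 18 rose and 0 fell, with 20 higher adjusted over the list alone (camera adjusted p = 8.64e-06, and adjusted p = 0.210 with an estimated correlation). Atf4, a factor of the integrated stress response, rose by 0.63 (SE 0.08) and Xbp1 by 0.55 (SE 0.08). Of 18 p53 targets and apoptosis regulators, 9 rose and 2 fell, with 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000134, and adjusted p = 0.0223 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, rose by 1.24 (SE 0.12) and the anti-apoptotic genes Bcl2 and Mcl1 by 1.12 (SE 0.11) and 0.64 (SE 0.07), while Ccng1 fell by 0.98 (SE 0.13). Of 10 cytokines and NF-kappaB targets, 5 rose and 0 fell, with 7 higher adjusted over the list alone (camera adjusted p = 0.000438, and adjusted p = 0.0405 with an estimated correlation). Relb rose by 1.21 (SE 0.12), and the chemokine gene Ccl2 rose by 3.42 (SE 0.44) at a Mock mean of only 2.25 counts. Growth factor rises numbered 5 without Mock replicate 2 or Pilo replicate 4, and falls 2 without Pilo replicate 1. Without Mock replicate 1 or 3 or Pilo replicate 2 or 4, the call of Nucb2 was lost and 1 p53 target was lower.

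Clock and chromatin genes were also among the rises. Of 20 circadian clock genes, 11 rose and 2 fell, with 12 higher and 3 lower adjusted over the list alone (camera adjusted p = 1.13e-05, and adjusted p = 0.0624 with an estimated correlation). The repressors Per1, Bhlhe40 and Cry1 rose by 2.01 (SE 0.19), 1.17 (SE 0.07) and 1.02 (SE 0.11). Of 39 chromatin modifiers, 14 rose and 4 fell, with 17 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.00100, and adjusted p = 0.173 with an estimated correlation). Kdm6b, a histone H3K27 demethylase, rose by 1.80 (SE 0.18), Arid5a by 1.39 (SE 0.12) and Tet3, a methylcytosine dioxygenase, by 0.87 (SE 0.07). Of 42 cytosolic ribosomal protein genes, 23 rose and 0 fell, with 31 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.13e-05, and adjusted p = 0.334 with an estimated correlation). Rpl4 rose by 0.60 (SE 0.07) and Rpl19 by 0.54 (SE 0.08). The clock falls numbered 0 without Mock replicate 1 and 1 without Mock replicate 2 or Pilo replicate 3 or 4, and 1 ribosomal protein gene was lower without Pilo replicate 1.

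Synaptic and channel genes rose and fell. Of 32 scaffold and adhesion genes, 8 rose and 2 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.0197, and adjusted p = 0.210 with an estimated correlation). Homer1, a postsynaptic scaffold, rose by 2.15 (SE 0.16), and Slitrk4, a synaptic adhesion protein, fell by 0.65 (SE 0.12). Of 27 synaptic vesicle and release genes, 9 rose and 1 fell, with 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.173 with an estimated correlation). Vamp2 and Snap25, both SNARE proteins of vesicle fusion, rose by 0.49 (SE 0.08) and 0.40 (SE 0.08). Of 27 sodium and calcium channel genes, 7 rose and 1, Scn2b, fell, with 6 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0795). Without Mock replicate 3 or Pilo replicate 3 this list passed (camera adjusted p = 0.0497 and 0.0437), and without any other library it did not. The AMPA receptor auxiliary subunit gene Cacng2 rose by 0.58 (SE 0.07). Of 45 potassium and HCN channel genes, 7 rose and 6 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.803, upward, with a mean of -0.01). Kcnn3, a calcium-activated channel, rose by 0.60 (SE 0.07) and Kcnv1 fell by 0.64 (SE 0.17). Of 25 glutamate receptor genes, Grin3b and Gria4 rose by 0.87 (SE 0.21) and 0.33 (SE 0.08), and Grm2, a presynaptic metabotropic receptor, fell by 0.59 (SE 0.07), with the same 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.519). Of 14 GABA receptor genes, 3 rose, among them Gabrg3 and Gabbr1, and 3 fell, among them Gabrd and Gabra2, with the same numbers adjusted over the list alone (camera adjusted p = 0.967). Gabrd, an extrasynaptic subunit, fell by 0.59 (SE 0.10). Over exons and introns together Gabrg3 did not pass (0.20, adjusted p = 0.108), nor did Nlgn3 of the scaffold list (0.02, adjusted p = 0.880). The call of Gabra2 was lost without Mock replicate 2 or 3 or Pilo replicate 4, at adjusted p up to 0.0601. Of 11 acetylcholine receptor genes, Chrna2 rose and Chrnb2 fell, with the same 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.803, upward, while the median was -0.02). Chrm3, a muscarinic receptor, had a log2 fold change of 0.24 (SE 0.09, adjusted p = 0.0503), and passed with the replicate number as a block (adjusted p = 0.00599). It also passed under RLE size factors and DESeq2 (adjusted p = 0.0458 and 0.0355) and without Mock replicate 3 or Pilo replicate 2 (adjusted p = 0.0269 and 0.0297). Under limma-voom and in the other fits without a library it did not pass. The fall of Chrnb2, by 0.22 (SE 0.07), was lost without Mock replicate 1, 2 or 3 or Pilo replicate 2 or 4, at adjusted p up to 0.111, with no filter on low counts, and over exons and introns together (-0.08, adjusted p = 0.377). Potassium and HCN channel falls numbered 1 without Mock replicate 1 and 3 without Mock replicate 3. GABA receptor rises numbered 1 without Mock replicate 2 or Pilo replicate 4, and falls 1 without Mock replicate 3 or Pilo replicate 4. Scaffold falls numbered 1 and vesicle falls 0 without Mock replicate 1, 3 or 4 or Pilo replicate 2 or 4. The call of Scn2b in exons was lost without Mock replicate 1, 2 or 3 or Pilo replicate 2 or 4, and under RLE size factors. Without Pilo replicate 1, falls numbered 4 in the glutamate receptor list, 3 in the sodium and calcium channel list and 2 in the vesicle list. Acetylcholine receptor rises numbered 2 without Mock replicate 3 or Pilo replicate 2, and 0 under the stricter filter, which left Chrna2 untested.

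**Figure D2:**
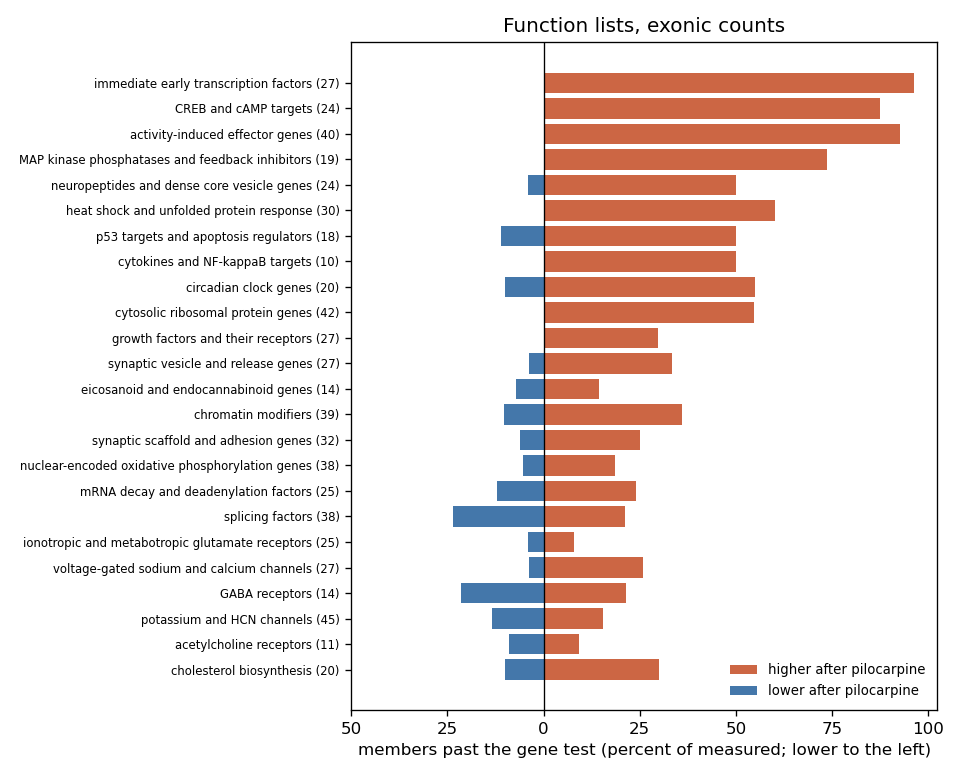
Share of measured members of each of the 24 function lists that were higher (right) or lower (left) after pilocarpine in the exonic counts, in percent, with the number measured in brackets. In immediate early transcription factors 26 of 27 members rose, while splicing factors had 8 higher and 9 lower of 38.

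RNA processing and metabolic genes went both ways. Of 38 splicing factors, 8 rose and 9 fell, with 11 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.595, downward, with a median of 0.10 and a mean of -0.03). The kinases Clk1 and Clk4, which phosphorylate SR proteins, fell by 0.92 (SE 0.09) and 0.74 (SE 0.08), and the SR protein genes Srsf6 and Srsf5 fell by 0.77 (SE 0.08) and 0.69 (SE 0.08). Of 25 mRNA decay and deadenylation factors, 6 rose and 3 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.192). Btg2 rose by 2.06 (SE 0.21) and Zfp36, which binds AU-rich elements, by 2.07 (SE 0.35), while Cnot3 fell by 0.59 (SE 0.08). Of 20 cholesterol biosynthesis genes, 6 rose and 2 fell, with 7 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.834, upward, while the median was -0.02 and the mean -0.05). Fdps fell by 1.52 (SE 0.22). Of 38 nuclear-encoded oxidative phosphorylation genes, 7 rose and 2 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.155), and Atp5g3 rose by 0.67 (SE 0.06). Of 14 eicosanoid and endocannabinoid genes, Ptgs2, which encodes cyclooxygenase-2, and Dagla rose by 1.96 (SE 0.15) and 0.55 (SE 0.09) and Daglb fell by 0.36 (SE 0.07), with the same 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0973). That list passed without Pilo replicate 1 (camera adjusted p = 0.0444) and without no other library. In all, 14 of the 24 function lists passed camera, and 6 passed with an estimated correlation. Splicing factor rises numbered 5 without Pilo replicate 2 or 4 and 13 without Pilo replicate 3. Decay factor falls numbered 1 without Mock replicate 3 or 4 or Pilo replicate 2, and cholesterol rises 2 without Mock replicate 2 or 4 or Pilo replicate 4. Oxidative phosphorylation falls numbered 4 without Pilo replicate 1.

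Falls were smaller than the largest rises. Nudt12, an NADH hydrolase, fell by 2.01 (SE 0.24), Tmem170 by 1.86 (SE 0.17) and Cox17, a copper chaperone of cytochrome c oxidase, by 1.82 (SE 0.17). Cox17 went from 31.6 ± 2.04 to 8.90 ± 2.65 CPM (SD, n = 4 each). Plau, the urokinase plasminogen activator, fell by 1.72 (SE 0.22), Slc40a1, the iron exporter ferroportin, by 1.62 (SE 0.29) and Ube2t by 1.55 (SE 0.24). Prrt2 fell by 1.67 (SE 0.23) in the exonic table, but over exons and introns its change was 0.15 with an adjusted p of 0.420. Among long noncoding RNA genes, 148 rose and 472 fell of 2447 tested, against 2686 and 2303 of 14806 protein-coding genes (Fisher's exact test of direction, two-sided, p = 1.28e-46). Protein-coding genes matched on expression, transcript length and GC content also fell more often than they rose, 348 against 179. So did genes of the annotation class TEC, 192 against 95, and all genes of the remaining classes, 140 against 65. The lean was thus not particular to long noncoding RNA.

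Across 19176 genes tested, 2994 rose and 3107 fell, of which 407 rose and 541 fell at least 2-fold. The 4 Pilo libraries did not overlap the 4 Mock libraries in 6131 genes, or 32.0%, where chance gives 2.86%. With the replicate number as a block, 4572 genes rose. Against a minimum change of 1.5-fold, 317 rose and 340 fell. The libraries also separated by replicate number in both groups, numbers 1 and 2 from 3 and 4 on the second principal component, and within those sets 1155 rose and 982 fell, and 1231 rose and 1199 fell.

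Counting whole gene bodies adds intronic reads, which were 29.2% to 33.7% of these counts, so likeness to the exonic result is partly built in. Counts in introns alone ask whether unspliced RNA shows the same changes. Over exons and introns together, 2823 of 14816 genes rose and 2693 fell, and with the replicate number as a block 4281 rose. In introns alone, 2609 of 13318 genes rose and 2911 fell. Exonic and intronic log2 fold changes correlated across genes (Pearson r = 0.794, Spearman rho = 0.753, 13047 genes, which are not independent replicates). Against a minimum change of 1.5-fold, 277 gene bodies rose and 226 fell. Within the sets of libraries named above, 1138 rose and 1070 fell, and 1249 rose and 1305 fell.

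Exonic and intronic changes were compared gene by gene, and 12 genes are named by rule. Srsf7, an SR splicing factor (Entrez gene 225027, chromosome 17, 80200080 to 80207369), rose in introns by 1.25 (SE 0.11), while its exonic change was -0.14 (SE 0.09), and its intronic share of counts went from 15.5% to 28.8% (group totals, 4 libraries each). The difference, 1.39 (SE 0.06), had an adjusted p of 7.79e-08. Clk1, Ddx5, an RNA helicase, and Srsf5 had an intronic change above the exonic by 1.12 (SE 0.06), 0.85 (SE 0.06) and 0.97 (SE 0.06), and all 3 fell in exons. Ina, a neuronal intermediate filament, and Ndfip1, an adaptor of ubiquitin ligases, rose in both regions, with differences of 1.12 (SE 0.08) and 0.89 (SE 0.06). In the other direction, Rbmx, an RNA-binding protein (Entrez gene 19655, chromosome X, 57383348 to 57393046), fell by 2.23 in introns (SE 0.15) and by 0.69 in exons (SE 0.10), a difference of -1.54 (SE 0.10), with its intronic share going from 14.1% to 4.54%. Rtn4r, the Nogo receptor, and Scn2b, a sodium channel subunit, had differences of -1.55 (SE 0.11) and -1.48 (SE 0.10). Pknox2, a homeobox factor, rose in exons and fell by 0.51 in introns (SE 0.08). Mrpl42 and D430019H16Rik rose in exons and fell in introns, with differences of -1.30 (SE 0.10) and -1.32 (SE 0.10).

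**Figure D3:**
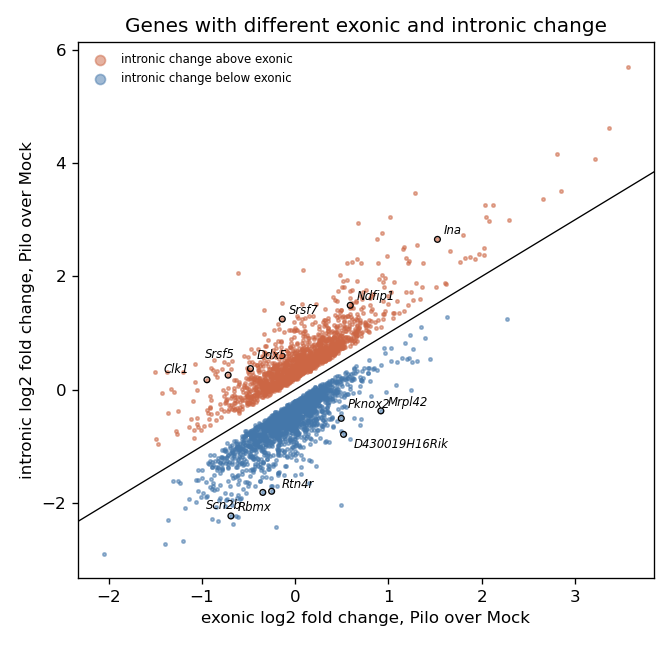
Exonic (horizontal) and intronic (vertical) log2 fold change, Pilo over Mock, of the 3420 genes whose changes differed between the regions, a point per gene, with the line of equal change and the 12 named genes circled. Of these genes, 1664 lie above the line and 1756 below it.

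Of 13047 genes tested in both regions, 1664 had an intronic change above the exonic change and 1756 below it, together 3420. With exonic and intronic counts of a library on a common scaling factor instead of a factor per region, the split was 406 against 5822 and the median difference of all genes -0.26, so the directions given here are relative to the average gene. Within the sets of libraries named above, 421 and 1002 genes differed. The intronic share of all counts was 33.0% ± 0.799 in Mock and 30.0% ± 0.627 in Pilo (SD, n = 4 each), a difference of -2.98 percentage points (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 can give). The share was lower in Pilo in all 4 same-numbered pairs, but an exact permutation test within the pairs did not pass (two-sided, p = 0.125, the smallest that 4 pairs can give). Within the sets, the difference was -2.16 and -3.81 points.

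**Figure D4:**
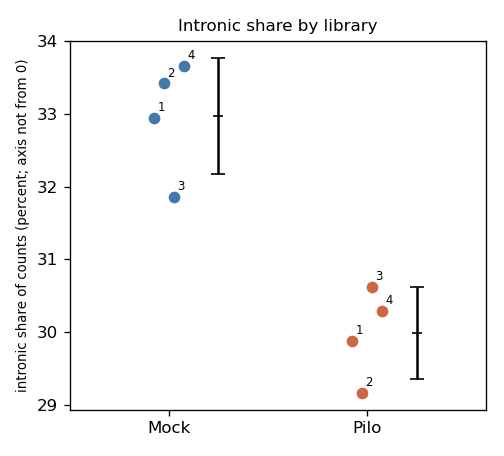
Intronic share of exonic plus intronic counts in percent (the axis does not start at 0), with a point per library, numbered as in the second table, and the mean ± SD of each group of 4. Mock libraries lie between 31.9% and 33.7% and Pilo libraries between 29.2% and 30.6%.

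Marker genes asked which cell types the captured nuclei held and whether they moved with the groups. Of 12 excitatory neuron markers, 5 rose and 2 fell, with 6 higher and 2 lower adjusted over the list alone. Slc17a6, a vesicular glutamate transporter, rose from 34.1 ± 3.90 to 54.9 ± 4.09 CPM and the transcription factor gene Neurod1 fell from 17.8 ± 0.583 to 11.2 ± 0.789 CPM (SD, n = 4 each). Of 10 deep layer markers, 6 rose, among them Hs3st4 and Tle4, with 6 higher and 1 lower adjusted over the list alone. Of 8 upper layer markers, Lamp5 rose and Pou3f2 and Calb1 fell, with the same 1 higher and 2 lower adjusted over the list alone (median 0.05, mean -0.06, camera downward). Of 8 hippocampal pyramidal markers, Pou3f1, Mpped1 and Wfs1 rose, of 8 dentate granule markers Pdzd2 fell, and of 12 striatal markers Ppp1r1b rose, each the same adjusted over the list alone. Of 8 thalamic markers, Rgs16, Ntng1, Lef1 and Tcf7l2 rose, with 5 higher adjusted over the list alone. Excitatory marker rises numbered 3 without Mock replicate 2 and 2 without Mock replicate 4, and falls 1 without Mock replicate 1 or 4 or Pilo replicate 4. Thalamic rises numbered 2 without Mock replicate 1 or 2 or Pilo replicate 3. The rise of Lamp5 was lost without Mock replicate 2 or 4 or Pilo replicate 1 or 4, with no filter on low counts and at thinned depth, and upper layer rises numbered 2 without Pilo replicate 3. The fall of Pdzd2 was lost without Mock replicate 1, 2 or 3 or Pilo replicate 2, 3 or 4, and with no filter on low counts. Without Pilo replicate 1, a dentate granule marker rose, 2 striatal markers rose and 1 fell.

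Markers of cells other than excitatory neurons were mostly higher in Pilo without passing the test. Of 16 GABAergic markers, Dlx2, Nxph1, Gad2, Gad1 and Lamp5 rose, with 7 higher adjusted over the list alone, and Gad2, an enzyme of GABA synthesis, went from 32.3 ± 5.09 to 43.6 ± 8.35 CPM (SD, n = 4 each). Of 13 astrocyte markers, S100b and Slc4a4 rose, and of 12 oligodendrocyte markers Mbp, a myelin protein, rose from 133 ± 14.9 to 208 ± 50.8 CPM (SD, n = 4 each), both lists with the same numbers adjusted over the list alone. The astrocytic glutamate transporter gene Slc1a2 stood at 766 ± 116 and 952 ± 116 CPM (adjusted p = 0.0600). Of 9 oligodendrocyte precursor markers, Olig2 rose, with 0 adjusted over the list alone and 2 at an unadjusted p under 0.05. Its call was lost without Mock replicate 1 or 2 or Pilo replicate 3 or 4 and with no filter on low counts, and 2 of the list rose without Mock replicate 3 or Pilo replicate 2. GABAergic rises numbered 1 without Mock replicate 1 or 2, 3 without Mock replicate 4 or Pilo replicate 2, 2 without Pilo replicate 3 or 4 and 9 without Pilo replicate 1. Astrocyte rises numbered 4 without Pilo replicate 2, and oligodendrocyte rises 3 without Pilo replicate 1 and 2 without Mock replicate 3 or 4 or Pilo replicate 2. Of 12 microglial markers Trem2 fell (median 0.11, mean 0.04, camera downward), and of 10 choroid plexus and ependymal markers Foxj1 rose, with the same numbers adjusted over the list alone. By edgeR, 0 of 12 endothelial and pericyte, 4 erythrocyte and 7 mitochondrially encoded genes passed, also adjusted over the list alone, with median log2 fold changes of 0.71, 0.82 and 0.25, and 1 erythrocyte gene had an unadjusted p under 0.05. DESeq2 and limma-voom also called 0 in these lists, 2 erythrocyte genes rose without Pilo replicate 2, and with the replicate number as a block 4, 3 and 5 genes rose. Pilo replicate 3 held 16.3 CPM of Flt1 and 4.02 of Tek, both endothelial, where the other Pilo libraries had at most 2.78 and 0.696. Of the 16 marker lists, 0 passed camera after adjustment (adjusted p from 0.172 to 0.996), 3 had an unadjusted p under 0.05, and fry called 2, the deep layer and hippocampal pyramidal lists (adjusted p = 0.0411 each). With the replicate number as a block 4 passed camera, the deep layer, astrocyte and oligodendrocyte lists at adjusted p = 0.0271 and the GABAergic list at adjusted p = 0.0437. Without Pilo replicate 1, the deep layer and GABAergic lists passed (adjusted p = 0.0363 each).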

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

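The tests of mitochondrial share, of the sets of replicate numbers and of a mislabelled Mock replicate 4 were chosen only after the results were seen. Among 382 groups of 4 libraries checked, 23 had a library far from the other 3 by Dixon's ratio of gap to range at its 95% critical value, where chance gives about 19.1, or 1 in 20. In Pilo replicate 1, Bdnf was high at 46.55 CPM (others 28.46 to 29.2), Plau at 2.913, Pdzd2 at 94.33 and Sdhb at 48.47, and Maff was low at 3.342 and Bhlhe40 at 154.4. In Pilo replicate 3, Flt1 was high at 16.26 CPM, Tek at 4.017, Mbp at 283.3, Gad2 at 56.02 and Pou3f1 at 15.78. In Pilo replicate 2, Ube2t was low at 0.4895 CPM, Kcnd2 at 77.73 and Slc1a2 at 779.8. In Pilo replicate 2 of the second table, which matches Pilo replicate 3 of the exonic table, intronic Srsf7 was low at 281 CPM; the other values here are exonic, with that table's numbers. In Pilo replicate 4, Nupr1l was low at 0.5966 and Arid5a high at 21.01 CPM. In Mock replicate 1, Maff was low at 0.199, Fgfr1 at 59.05 and Kcnn3 at 36.42 CPM. In Mock replicate 4, Cdkn1a was high at 15.39 and Sdhb low at 51.63 CPM, and in Mock replicate 3 a noncoding gene of chromosome 17 was high at 4.181 CPM.

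The intronic share was 2.98 percentage points lower in Pilo. Without the 100 genes of highest mean count, which held 11.0% of counts, the difference was -3.22 points, which argues against a few abundant genes. Each set of replicate numbers held 2 libraries of each group, so a shift shared by all libraries of a set falls on both groups alike. Such a shift could not by itself give this difference. Within the sets the difference was -2.16 (SE 0.661) and -3.81 points (SE 0.576), but this test could not have favoured such a cause. Cytoplasmic RNA carried over with the nuclei cannot be told apart from a change in the nuclei. The mitochondrially encoded share differed by 0.00336 points with overlapping groups (exact permutation p = 0.629), though 5 of its 7 genes were higher with the replicate block, and the ribosomal protein share was 0.178% in Mock and 0.200% in Pilo (exact permutation p = 0.0571); a change in transcription or splicing during seizure stays open and untested.

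Some early gene counts were higher in Mock replicate 4 than in the other Mock libraries, with Fos at 29.24 CPM against 8.293 to 12.72. By Dixon's ratio Fos and Arc were not far from the others there. Of the genes checked, only Cdkn1a was far on the high side in that library. Rising genes of Mock replicate 4 lay 0.0635 of the way to the Pilo level (median of 293 genes, SE 0.0077), which argues against a mislabelled Pilo sample. Mixing with RNA of a Pilo sample stays open, since falling genes were displaced too, by 0.162 (334 genes, SE 0.0160), and early factors by 0.0918 (21 genes, SE 0.0367). A single share of mixed RNA would move rising and falling genes alike, and falling genes were also displaced in Mock replicate 2, by 0.0874 against 0.0104 for rising genes. In Mock replicates 1 and 3 the falling genes stood at -0.0124 and 0.00186. A mouse with more neuronal activity may also account for the early gene counts of Mock replicate 4, which was not tested.

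Of the long noncoding RNA genes past the test, 76.1% were lower, against 46.2% of protein-coding genes. Over 10 kb from any protein-coding gene, 84.4% were lower (76 lower and 14 higher, Fisher's exact p = 1.24e-13), which argues against reads of nearby coding genes. Protein-coding genes matched on GC content, transcript length and expression were lower in 66.0% (348 against 179), so these properties stay open as the source of most of the difference, though the matched share still lay below that of the noncoding genes (Fisher's exact p = 0.000181). Transcript length stayed unequal after matching, by -0.251 SD. The lean was not particular to long noncoding RNA, since genes of the TEC class and of the remaining classes also fell more often than they rose. A biological difference was not tested.

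Of the 35 splits of the 8 samples into groups of 4, 1, the real split, gave as many genes higher in exons (2994, highest other 202) and lower in exons (3107, highest other 0). The same held for genes higher (2823, highest other 188) and lower (2693, highest other 1) in gene bodies and different between regions (3420, highest other 2). A split that ignores the pairs would thus give such counts in 1 of 35 cases. Splits that mix the treatments carry the treatment effect as spread within their sides, which lowers their counts. With the numbers taken as pairs only 8 splits remain, so chance is not excluded there. The splits with 202 and 188 genes parted the libraries by replicate number, 1 and 2 from 3 and 4 of the exonic table. For the 14 function lists passing camera, chance was not excluded by this count, since 5 of the 35 splits gave as many, the highest other 17. The 4 others each set 3 libraries of 1 treatment against 3 of the other and so carry part of the real contrast, while the 18 splits with 2 libraries of each treatment per side gave at most 8. Among the 8 splits that part all pairs, which are too few for a share under 0.05, the highest other was 0 for each of the gene counts and 17 for the lists.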

How the results depend on the processing

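The fits within sets of replicate numbers, all alternatives for the intronic share and the counts of list members under the alternatives were chosen after the results were seen; the other alternatives were planned. Exonic counts of 2994 genes higher and 3107 lower lay within 1.5 times of these under RLE, DESeq2, limma-voom, either filter and thinned depth. With the replicate block, 4572 genes were higher in exons and 4281 in gene bodies, while 4443 and 3712 were lower. The block takes up the variation shared by same-numbered libraries. It also brought 4 marker lists and 6 genes named by the rule past the test and ended no call of those genes or of the lists. A minimum change of 1.5-fold, a stricter hypothesis by construction, left 317 higher and 340 lower in exons and 277 and 226 in gene bodies. With replicates 1 and 2 of the exonic table and the matching columns of the second only, fewer samples gave 1155 and 982 in exons, 1138 and 1070 in gene bodies and 421 genes that differed between regions. With 3 and 4 only, they gave 1231 and 1199, 1249 and 1305, and 1002. All 6101 genes called in exons kept their direction with replicates 1 and 2 only, as did the 6100 tested with 3 and 4 only, which is partly built in because the calls came from the same libraries. The intronic share differed by -2.16 and -3.81 points in these sets, and the cause was not tested. With the replicate block its difference stayed at -2.98 points and did not pass (exact permutation p = 0.125), since 4 pairs can give no smaller p. A common scaling factor for both regions gave 6228 genes instead of 3420, since it leaves the shift in intronic share in every gene. With an estimated correlation, 6 function lists passed instead of 14, and fry, which compares no list with other genes, called 19. Marker lists passing went from 0 to 2 with fry. With each library left out, ranges were 2487 to 3113 and 2356 to 3166 (exons), 2369 to 2863 and 2132 to 2839 (gene bodies), 2580 to 3375 (regions), -3.36 to -2.71 points (share), 14 to 15 (function lists) and 0 to 2 (marker lists, 2 without Pilo replicate 1). Prrt2 fell by 1.67 in exons and stood at 0.15 in gene bodies (adjusted p = 0.420), and the cause was not tested. Of the genes named by the rule, 3 lost their call in gene bodies (Gabrg3, Chrnb2 and Nlgn3), and Gabra2 and Chrnb2 lost it in 3 and 5 fits without a library. What depth alone limits was tested only by thinning to equal depth (2936 and 3078 in exons). Simulated exonic counts with 4 samples per group and 200 changed genes gave back 50.8% of 1.5-fold changes. Far more genes were called in the real data, so this rate does not give the sensitivity there.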

Other observations

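The grouping of genes by length was chosen after the results were seen, and it tests no explanation. Of 530 protein-coding genes longer than 300 kb, 25.5% rose and 2.45% fell, with a median log2 fold change of 0.14. Of 4699 genes of 10 to 30 kb, 14.1% rose and 21.2% fell, and of 737 genes up to 3 kb, 22.9% rose and 10.9% fell. Exonic and intronic calls had opposite directions in 49 genes, of which 29 were lower in exons and higher in introns and 20 the converse. Both regions rose in 1548 genes and fell in 1731.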
